A study of Rattus norvegicus with 6 samples.

How the data were processed

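Small RNA was sequenced from rat hearts. Per the labels' protocols, total RNA was extracted with Trizol, adaptors were ligated to both ends, the product was amplified by PCR, and fragments matching small RNAs were size selected before sequencing on an Illumina NextSeq. The series holds 3 normal hearts and 3 hearts in which the left anterior descending coronary artery had been tied for 0.5 h and released for 0.5 h. Groups and replicate numbers were taken from the sample labels. The labels number the hearts and give no other identity, so p-values measure the spread between these hearts.

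The deposited tables list 1257 rows, each a mature miRNA with its precursor, and cover 1191 mature IDs. Of these, 699 carry miRBase names and 492 are entries that the authors' table marks as predicted. Predicted entries are described by the size of their change; their deposited names are not printed here, and no coordinates are given. Per the submitters' processing notes, Novoalign 2.07.11 was used; its role, the genome build, the miRBase release, the mismatch limit and the method that predicted entries are not given in the sources used here. The deposited counts are raw tag counts per library, with separate columns, per the file headers, for the exact mature sequence, the most abundant sequence and all isoforms. Blank cells were read as 0. The smallest count listed was 2, so tags seen less often are missing in every library. Values in the authors' normalized table are whole numbers and are treated as a score. For the exact mature sequence, 100% of them equal the deposited count times 1 factor per library within 0.5 plus 0.1%. For all isoforms, 36.4% to 69.2% per library do. In normal replicates 1 to 3, 179, 232 and 256 counted rows are blank there, the highest at 31 counts, against 0 rows in each ischemia-reperfusion library; other rows with few counts are listed. These values enter the authors' comparison and the alternative that uses them. The authors' deposited comparison gives group means as a score with 10 added, a fold (the ratio of these means), a p-value and a false discovery rate for 589 rows. It also repeats 18 columns of normalized values per sample that were not used.

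All-isoform counts were analysed, because the authors' comparison rests on the normalized form of the same columns; this choice was made after the tables were seen. Where a mature ID was listed with several precursors, the row with the highest total was kept, since such rows hold nearly the same tags. Total counts per library over these rows ranged from 1376947 to 8429988. Tests ran in R 4.3.3 with edgeR 4.0.16: filterByExpr with the groups (minimum count 10), TMM factors, and the robust quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. CPM use library sizes times TMM factors. 21 lists of miRNAs (cell types, families, genomic clusters and a list from the ischaemia literature) were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, which held for 18 lists. Fry and camera with an estimated correlation were run beside it. Library composition was compared with two-sided exact permutation tests, whose smallest p with 3 libraries against 3 is 0.1, adjusted over 10 measures. Shares of counts in single libraries have 95% Wilson intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

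The miRNAs named in the text follow a rule fixed before the data were examined, as were the groups, lists and tests. It takes, among miRNAs past adjusted p 0.05 with a mean of at least 10 CPM and groups that do not overlap, the 8 with the largest log2 fold change in each direction (with a fill to 5 that was not needed); the 8 most abundant miRNAs; 20 fixed miRNAs; and the 4 members with the smallest p of each list past the test. Other miRNAs that are named were chosen after their values were seen.

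The test was tried on simulated data drawn from the real means, library sizes and dispersions, with 200 miRNAs changed. Among the 496 that passed the filter, it recovered 24.2% of those changed by 1 log2 unit, 72.3% at 2 units and 100% at 4 units, and called 0.322% of those unchanged. Simulated changes went up and down about equally often, unlike the real calls. These rates therefore do not cover wrong calls from scaling factors shifted by changes that mostly go the same way. A simulated fall of the let-7 list by 1 log2 unit was called, and no other of the 18 lists was. All other entries were unchanged in that draw, unlike in the real data. It therefore does not show how often camera calls lists wrongly against a background in which many entries rise. The sequences of 5S and 5.8S ribosomal RNA used in the closing section were written from general knowledge of mammals after the predicted entries had been seen. Alternatives were other scaling factors (RLE, upper quartile, total counts), DESeq2 1.42.0, limma-voom and limma on log2(normalized value + 1) with limma 3.58.1, other filters, a minimum change of 1 log2 unit, no robust estimation, the replicate number as a block and each library left out. Added after the data were seen were the other count columns, every precursor row, 1 row per mature sequence, miRBase-named miRNAs alone, scaling on miRBase-named miRNAs, and tests after thinning of each library to the smallest total; numbers of detected miRNAs after thinning had been planned. Figures and summaries used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.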

Results

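Mature miRNAs were profiled by small RNA sequencing in 3 normal rat hearts and 3 hearts after 0.5 h of coronary ligation and 0.5 h of reperfusion. Total all-isoform counts were 6963312, 8259263 and 8429988 in normal replicates 1 to 3, and 1376947, 2186243 and 2814802 in ischemia-reperfusion replicates 1 to 3. Every ischemia-reperfusion library was thus shallower than every normal library (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows; adjusted p = 0.2), so depth and group go together in the comparisons that follow. Names are given without the species prefix. No genome positions are given, since the build is not given in the sources used here.

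In all 6 libraries the most abundant miRNA was miR-1b, a member of the muscle miR-1 family, with 16.1% to 25.3% of the counts. It averaged 213627 ± 34814 CPM (SD, n = 3) in normal hearts and 194407 ± 48541 CPM (SD, n = 3) after ischemia-reperfusion. Next by mean CPM over the libraries came miR-143-3p, known from smooth muscle, at 130380 ± 12268 and 119335 ± 3974 CPM (SD, n = 3 each). Endothelial miR-126a-3p was at 88543 ± 28970 CPM in normal hearts and 57712 ± 4081 CPM after ischemia-reperfusion, and miR-99a-5p at 92537 ± 30075 and 55411 ± 3943 CPM (SD, n = 3 each). The other abundant miRNAs, miR-148a-3p, miR-26a-5p and miR-30a-5p, had log2 fold changes of -0.32, 0.15 and -0.06. The sign turned positive with factors from miRBase-named miRNAs for miR-1b (0.19), miR-143-3p (0.23), miR-148a-3p (0.04) and miR-30a-5p (0.30), and negative with upper-quartile factors for miR-26a-5p (-0.36). None of these 7 passed the edgeR test (adjusted p = 0.0532 for miR-99a-5p, 0.0905 for miR-126a-3p and 0.238 to 0.730 for the rest). Without normal replicate 1, miR-99a-5p (adjusted p = 0.00766), miR-126a-3p (0.00948) and miR-148a-3p (0.0224) passed as lower. With upper-quartile factors these 3 (0.00345, 0.00419 and 0.0211) and miR-143-3p (0.0277) did, and with no filter miR-99a-5p (0.0104) and miR-126a-3p (0.0220). In counts of the most abundant sequence miR-99a-5p passed (0.0356), and miR-26a-5p passed as higher with total counts (0.0493) and with factors from miRBase-named miRNAs (0.0150). The sign also turned without ischemia-reperfusion replicate 1 for miR-1b (0.10) and miR-30a-5p (0.031), without ischemia-reperfusion replicate 3 for miR-143-3p (0.035) and miR-30a-5p (0.058), and without normal replicate 1 for miR-26a-5p (-0.0083). The eighth, miR-1-3p, held 14.4% of the counts in normal replicate 1 and between 2.38% and 3.27% in the other 5 libraries. Its log2 fold change was -1.51 (edgeR adjusted p = 0.112) with that library and -0.36 (0.152) without it, and it passed without normal replicate 3 (adjusted p = 0.0440) and with upper-quartile factors (0.0273). miR-1-3p and miR-1b differ by G17A, counted from the 5′ end of miR-1-3p, so the split of reads between them is uncertain. The same holds for miR-99a-5p and miR-100-5p, for miR-30a-5p, miR-30d-5p and miR-30e-5p, for miR-133a-3p and miR-133b-3p, for miR-29a-3p and miR-29c-3p, for miR-23a-3p and miR-23b-3p, and for miR-450a-5p and miR-450b-5p.

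The 10 most abundant miRNAs held 75.7% ± 0.794 of counts in normal libraries and 71.7% ± 2.02 after ischemia-reperfusion (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.2). At least 1 count was found for 699 ± 40.2 miRNAs in normal and 727 ± 11.9 in ischemia-reperfusion libraries (SD, n = 3 each; exact permutation p = 0.4), and at least 10 counts for 464 ± 21.4 and 462 ± 25.1 (exact permutation p = 1.0). These numbers depend on depth. After thinning to the smallest total the groups did not overlap, with 558 to 588 miRNAs in normal and 692 to 726 in ischemia-reperfusion libraries at 1 count or more, and 290 to 297 against 359 to 453 at 10 or more. Predicted entries, which the authors' table lists beside miRBase-named miRNAs, took 1.29%, 1.09% and 1.18% of the counts in normal replicates 1 to 3. They took 13.6%, 7.87% and 5.46% in ischemia-reperfusion replicates 1 to 3 (exact permutation p = 0.1, adjusted p = 0.2). This last measure was added after the data were seen. The 95% Wilson intervals of the shares given for single libraries reached at most 0.0624 percentage points to either side.

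**Figure D1:**
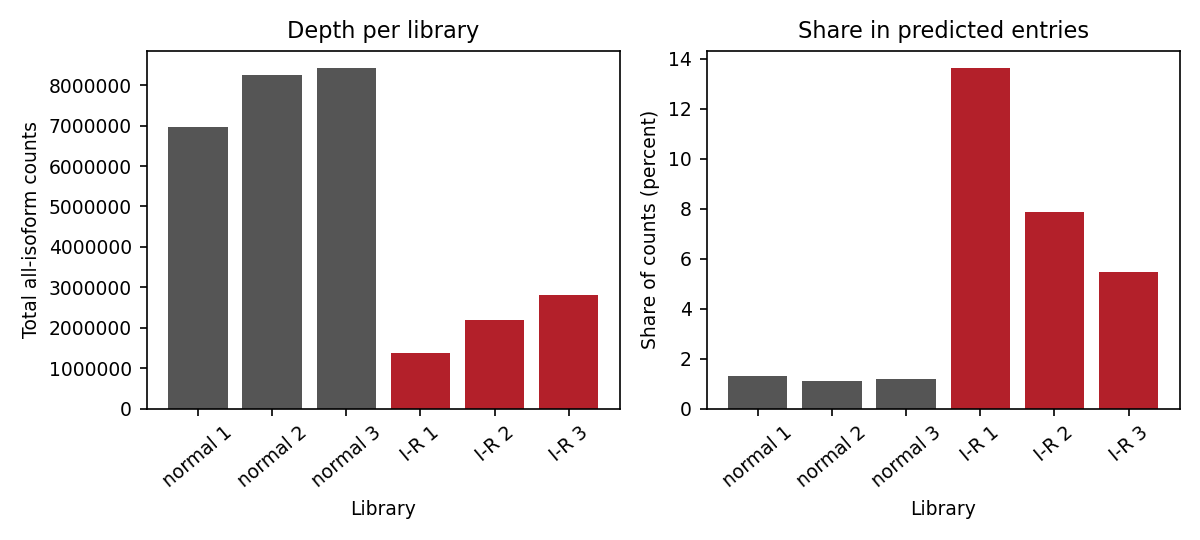
Total all-isoform counts (left) and the share of those counts in predicted entries in percent (right), 1 bar per library, normal in grey and ischemia-reperfusion (I-R) in red. All I-R libraries are shallower than the normal ones, and their predicted share, from 5.46% to 13.6%, lies above the 1.09% to 1.29% of the normal libraries.

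The main comparison asked which miRNAs differ between normal hearts and hearts early in reperfusion. Of 524 entries tested, 224 passed adjusted p 0.05 in edgeR's quasi-likelihood test, and the 2 classes of entry moved apart. Among 219 predicted entries, 172 were higher and 7 lower after ischemia-reperfusion, while among 305 miRBase-named miRNAs 3 were higher and 42 lower. The median log2 fold change was 4.55 over tested predicted entries (4.53 with the 14 entries without counts in normal libraries set to a floor of 3 counts over that group) and -0.40 over miRBase-named miRNAs. The counts of calls among miRBase-named miRNAs depend on scaling. With factors from miRBase-named miRNAs, their median was -0.05, with 14 higher and 13 lower. With total counts it was -0.16, with 10 higher and 16 lower, and with upper-quartile factors -0.89, with 3 higher and 145 lower. When miRBase-named miRNAs were fitted alone, 5 were higher and 3 lower. The count of 42 lower became 67 without normal replicate 1, 19 without normal replicate 2, 27 without normal replicate 3, 21 without ischemia-reperfusion replicate 1 and 8 without ischemia-reperfusion replicate 2. The count of 3 higher became 5 without normal replicate 1 and 7 without ischemia-reperfusion replicate 3. The count of 7 predicted entries lower became 17 with upper-quartile factors, and 4 with total counts or factors from miRBase-named miRNAs. It was also 4 without normal replicate 3 or without ischemia-reperfusion replicate 1.

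**Figure D2:**
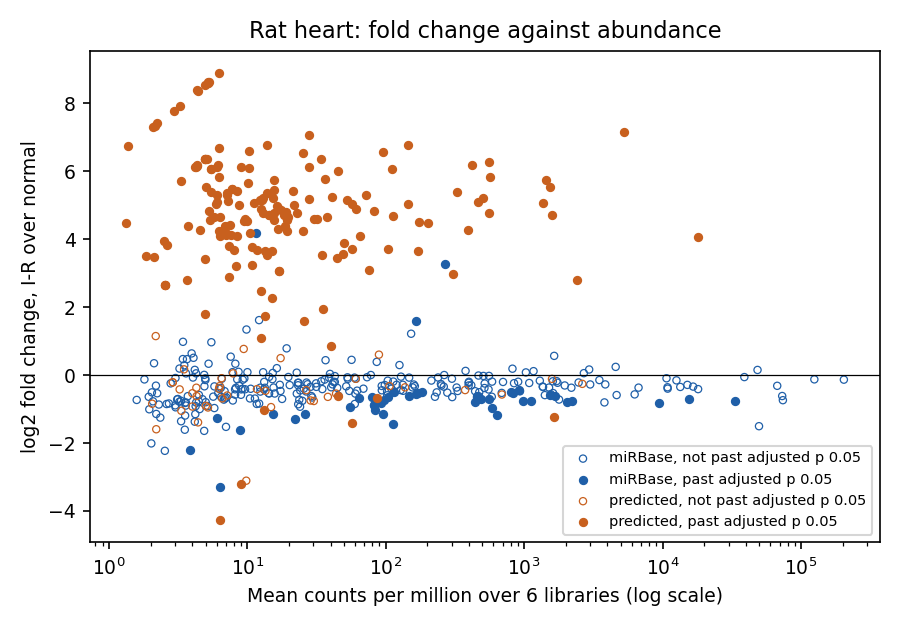
Log2 fold change (ischemia-reperfusion over normal) of the 524 tested entries against their mean CPM over 6 libraries on a log axis, miRBase-named in blue and predicted in orange, filled where adjusted p was under 0.05. The predicted entries lie mostly above 0 (172 higher, 7 lower), and the filled miRBase-named ones mostly below it (3 higher, 42 lower, or 14 higher and 13 lower with factors from miRBase-named miRNAs), and entries without counts in normal libraries form the diagonal at the top left, where fitted values are no bound.

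The 3 miRBase-named miRNAs called higher were miR-1949, miR-3068-3p and miR-122-5p; miR-1949 and miR-3068-3p were chosen after their values were seen. miR-1949 was at 1.21 ± 0.253 CPM in normal hearts and 22.04 ± 2.83 CPM after ischemia-reperfusion (SD, n = 3 each), a log2 fold change of 4.17 ± 0.41 (SE; adjusted p = 0.00125), and passed under each of the 24 alternatives. miR-3068-3p was at 82.8 ± 14.5 and 246.9 ± 44.0 CPM (SD, n = 3 each; log2 fold change 1.58 ± 0.22, SE; adjusted p = 0.00254). Counted by its exact mature sequence alone, miR-3068-3p had a log2 fold change of 0.13 (adjusted p = 0.827), and counted by its most abundant sequence 3.74, so the rise was in counts of sequences other than the listed one. miR-122-5p, the main miRNA of liver cells, was at 50.5 ± 28.1 CPM in normal hearts and at 866.9, 510.2 and 79.1 CPM in ischemia-reperfusion replicates 1 to 3 (log2 fold change 3.26 ± 0.86, SE; adjusted p = 0.0202). The groups overlapped, and the call was lost without normal replicate 2 (adjusted p = 0.0637), normal replicate 3 (0.0640) or ischemia-reperfusion replicate 1 (0.0548), and when miRBase-named miRNAs were fitted alone (0.188).

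Among the miRNAs that fell, miR-195-3p had the largest log2 change of those named by size. It went from 164 ± 18.4 to 60.2 ± 8.10 CPM (SD, n = 3 each), a log2 fold change of -1.45 ± 0.19 (SE; adjusted p = 0.00217). miR-128-3p, best known from neurons, went from 879 ± 112 to 388 ± 15.99 CPM (log2 fold change -1.18 ± 0.15, SE; adjusted p = 0.00217). miR-674-3p went from 132 ± 29.1 to 59.5 ± 5.17 CPM (log2 fold change -1.15 ± 0.21, SE; adjusted p = 0.00531). These 3 are the miRBase-named miRNAs also called lower when that class was fitted alone, at -1.10, -0.83 and -0.80 (adjusted p = 0.00232, 0.0183 and 0.0426). miR-340-3p (-1.28), let-7b-3p (-1.15) and miR-204-5p (-1.14) fell with adjusted p of 0.0122, 0.00949 and 0.0452 and did not pass in that fit (0.0610, 0.0725 and 0.231). The call of miR-340-3p was also lost without normal replicate 2 (0.0621) or ischemia-reperfusion replicate 2 (0.0588), and that of miR-204-5p without any library but ischemia-reperfusion replicate 1 (0.0678 to 0.159). In exact mature sequence counts miR-674-3p did not pass (adjusted p = 0.256). The 2 predicted entries in this group fell by 1.41 and 1.24 on the log2 scale (adjusted p = 0.00945 and 0.00761).

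**Figure D3:**
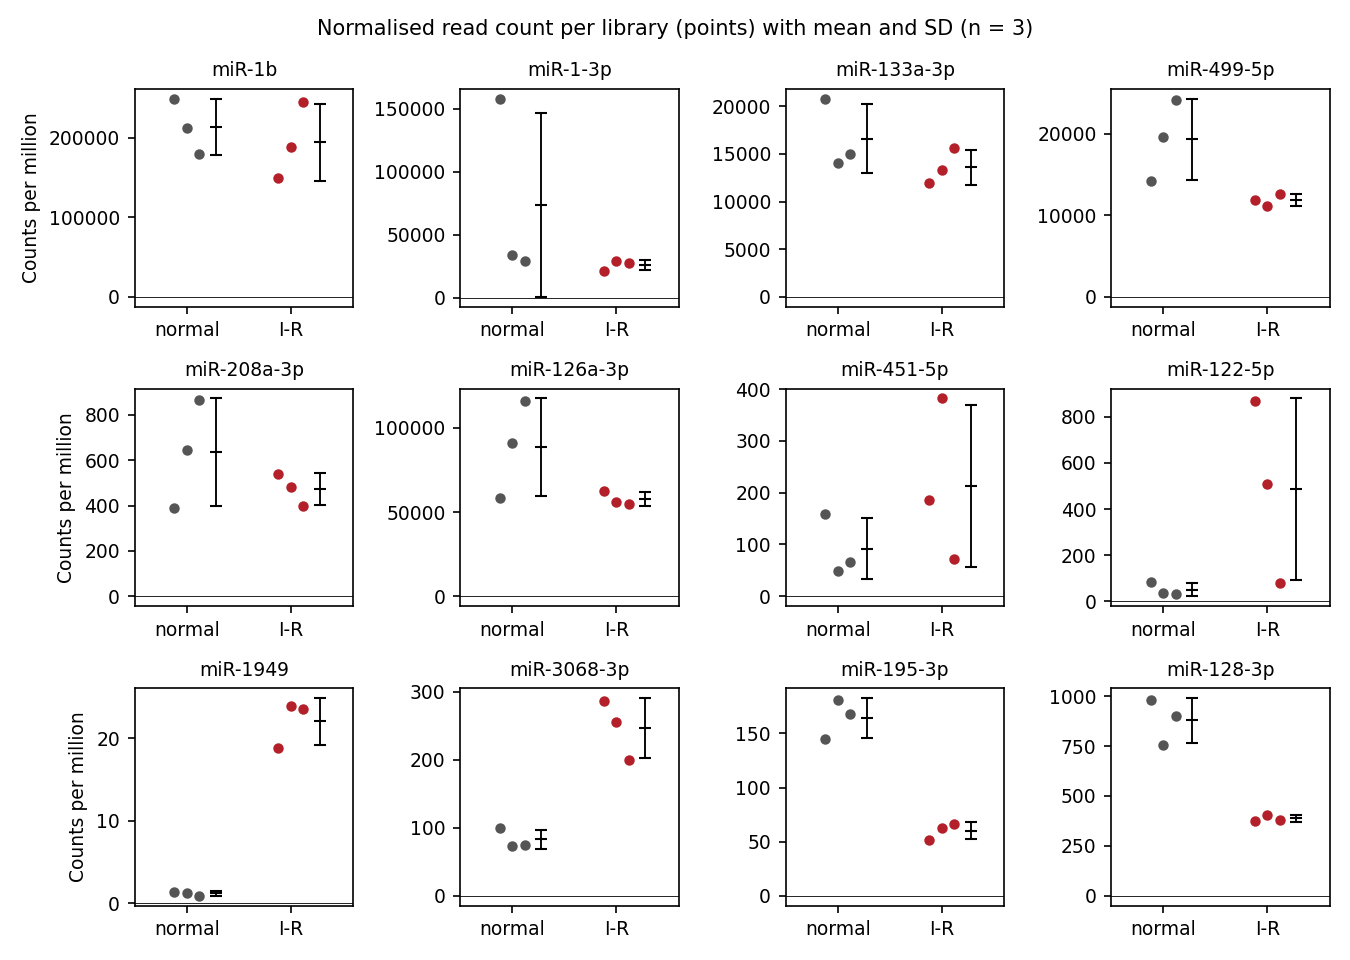
Normalised read count in CPM for 12 miRNAs, points for the 3 normal and the 3 ischemia-reperfusion (I-R) libraries, with the mean and SD beside them (n = 3); each panel has its own linear axis. miR-195-3p, miR-128-3p, miR-1949 and miR-3068-3p separate the groups, miR-1-3p has 1 high normal library, and miR-122-5p ranges from 79.1 to 866.9 CPM after I-R.

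The heart muscle list showed no member that rose. Of its 9 tested members, 2 fell, miR-499-5p, encoded in a cardiac myosin gene (19332 ± 4956 to 11869 ± 709 CPM, SD, n = 3 each; log2 fold change -0.70 ± 0.21, SE; adjusted p = 0.0307), and miR-133a-5p (log2 fold change -0.65; adjusted p = 0.0278). The other 7 did not pass, among them miR-133a-3p at 16619 ± 3643 and 13595 ± 1853 CPM (adjusted p = 0.279) and miR-208a-3p at 634 ± 238 and 473 ± 69.4 CPM (SD, n = 3 each; adjusted p = 0.290). Both passed as lower with upper-quartile factors (0.0320 and 0.0173), miR-208a-3p passed without normal replicate 1 (0.0284), and miR-133a-3p turned to 0.049 with factors from miRBase-named miRNAs. Adjusted over the list alone, 0 members passed. The list leaves out miR-1b. Without miR-1b, the list held 17.8%, 6.65% and 6.42% of counts in normal replicates 1 to 3 and 5.29% to 6.25% after ischemia-reperfusion (exact permutation p = 0.1, adjusted p = 0.2), with the high value of miR-1-3p in normal replicate 1. The sum of miR-1-3p and miR-1b overlapped between the groups. It was 187424 to 370731 CPM of the library total in normal hearts and 191227 to 280580 after ischemia-reperfusion. The share with miR-1b included was not tested. The camera test of the list gave adjusted p = 0.0836. The list passed camera downward without normal replicate 1 (0.0452), without normal replicate 3 (0.0487) and with no filter (0.0274). Fry also passed it (0.0327), while camera with an estimated correlation did not (0.481). Both falls were lost when miRBase-named miRNAs were fitted alone (adjusted p = 0.357 for miR-499-5p and 0.328 for miR-133a-5p), and miR-499-5p was also lost with total counts (0.123) and without any library but normal replicate 1 (0.0634 to 0.112). The fall of miR-133a-5p was also lost without normal replicate 2 (0.0791), normal replicate 3 (0.0550), ischemia-reperfusion replicate 1 (0.0890) or ischemia-reperfusion replicate 2 (0.0881). The skeletal muscle miRNA miR-206-3p was at 573 ± 126 and 371 ± 64.2 CPM (SD, n = 3 each; adjusted p = 0.0560), and as the 1 tested member of its list it passed adjusted over the list alone. It also passed without normal replicate 3 (0.0397), with no filter (0.0326) and with upper-quartile factors (0.00940).

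Markers of other cells in the heart were measured beside these. Neither of the 2 endothelial members passed edgeR (1 had an unadjusted p under 0.05; DESeq2 and limma-voom passed 0), and the endothelial share of counts was 8.28% ± 2.60 and 6.42% ± 0.703 (SD, n = 3 each; exact permutation p = 0.4, adjusted p = 0.5). The erythroid share was 0.251% ± 0.0145 and 0.190% ± 0.0206 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, adjusted p = 0.2), and the leukocyte share 0.0616% ± 0.00551 and 0.0579% ± 0.00349 (SD, n = 3 each; exact permutation p = 0.3, adjusted p = 0.5). Most of the erythroid share was miR-486, which is also present in muscle, so the lower share does not single out red cells. Of 7 smooth muscle and fibroblast members, miR-145-3p fell (log2 fold change -0.51; adjusted p = 0.0205) and 6 did not pass. The median of the 7 was -0.11, and it turned positive with RLE factors (0.01), total counts (0.14) and factors from miRBase-named miRNAs (0.25). Of 7 leukocyte members, miR-142-5p fell (-0.63; adjusted p = 0.0248), while miR-142-3p (71.6 ± 20.6 and 49.1 ± 6.49 CPM), the myeloid miR-223-3p (11.1 ± 3.70 and 8.20 ± 2.06 CPM) and miR-155-5p (20.3 ± 2.84 and 19.3 ± 9.83 CPM; SD, n = 3 each) did not pass (adjusted p = 0.144, 0.453 and 0.918). miR-142-3p passed as lower without normal replicate 1 (0.0273) and with upper-quartile factors (0.00933). The log2 fold change of miR-155-5p, -0.06, turned positive with RLE factors (0.025), total counts (0.16), factors from miRBase-named miRNAs (0.25) and without ischemia-reperfusion replicate 1 (0.34). Of 3 red cell members, miR-486, also present in muscle, fell from 2599 to 1511 CPM (log2 fold change -0.78; adjusted p = 0.0103), and 2 did not pass, among them miR-451-5p at 91.9 ± 59.0 and 213 ± 157 CPM (SD, n = 3 each; adjusted p = 0.195). The median of the 3 was -0.41 and camera pointed downward, while their mean was 0.0065. miR-144-3p had between 2 and 9 counts per library and was not tested. In the liver and epithelial list miR-122-5p rose and the other 7 did not pass. Its median of -0.05 and camera pointed downward, while its mean of 0.61 and fry pointed upward, and the median turned positive with RLE factors (0.07), total counts (0.19) and factors from miRBase-named miRNAs (0.30). In the neural and endocrine list miR-128-3p fell and 6 did not pass, and the median of -0.03 turned positive with the same 3 scalings (0.07, 0.21 and 0.31). Adjusted over the list alone, 1 erythroid and 1 neural and endocrine member passed, and 0 of the endothelial, smooth muscle and fibroblast, leukocyte, and liver and epithelial lists. None of the 5 cell type lists with at least 3 tested members passed camera (adjusted p = 0.0836 for leukocyte, 0.327 for smooth muscle and fibroblast, 0.331 for neural and endocrine, 0.347 for erythroid and 0.635 for liver and epithelial). The leukocyte list passed camera downward without ischemia-reperfusion replicate 3 (0.0320) and with no filter (0.0297). Fry also passed it (0.0402), while camera with an estimated correlation did not (0.481). The falls of miR-145-3p and miR-142-5p were lost without normal replicate 2 or any ischemia-reperfusion library (adjusted p = 0.0636 to 0.101 and 0.0831 to 0.106), and that of miR-486 without ischemia-reperfusion replicate 2 (0.0588). All 3 of these falls were also lost when miRBase-named miRNAs were fitted alone (edgeR adjusted p = 0.582, 0.433 and 0.0972).

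No member of the hypoxia and inflammation lists passed edgeR's test. miR-210-3p, the miRNA most often linked to hypoxia, was at 515 ± 201 CPM in normal hearts and 370 ± 34.7 CPM after ischemia-reperfusion (SD, n = 3 each; log2 fold change -0.47 ± 0.29, SE; adjusted p = 0.235). It passed as lower without normal replicate 1 (0.0330) and with upper-quartile factors (0.0148), and was at 0.19 in exact mature sequence counts. None of 10 inflammation members passed edgeR, with 1 under an unadjusted p of 0.05, 1 past DESeq2 and 0 past limma-voom (camera adjusted p = 0.0836). The inflammation list passed camera downward without ischemia-reperfusion replicate 3 (0.0312) and with no filter (0.0346), and not with an estimated correlation (0.481). Adjusted over the list alone, 0 members of the hypoxia and inflammation lists passed. Of these, miR-21-5p was at 11027 ± 1186 and 10320 ± 1609 CPM, and miR-146a-5p at 3287 ± 450 and 2712 ± 284 CPM (SD, n = 3 each; adjusted p = 0.642 and 0.211). miR-34a-5p, miR-320-3p, miR-29a-3p, miR-15b-5p and miR-195-5p had log2 fold changes of -0.36, -0.31, -0.28, 0.06 and -0.34 and adjusted p of 0.139 to 0.907. With factors from miRBase-named miRNAs the sign turned for miR-21-5p (0.25), miR-146a-5p (0.075), miR-320-3p (0.034) and miR-29a-3p (0.081), and when that class was fitted alone also for miR-195-5p (0.0011). miR-21-5p was above 0 in 10 alternatives, among them RLE factors (0.019), total counts (0.14) and the fit without ischemia-reperfusion replicate 1 (0.053). miR-15b-5p turned negative with upper-quartile factors (-0.47) and without normal replicate 3 (-0.27). With upper-quartile factors miR-34a-5p (adjusted p = 0.0151), miR-320-3p (0.0321), miR-29a-3p (0.0232), miR-195-5p (0.0279) and miR-146a-5p (0.0249) passed as lower.

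Of 18 lists tested with camera, 2 passed, both downward, against a background that includes the predicted entries. Both calls were lost with an estimated correlation (adjusted p = 0.481 for each). In the list from the ischaemia-reperfusion literature, 6 of 29 tested members fell and 23 did not pass (camera adjusted p = 0.0164; 0 members adjusted over the list alone). The 4 with the smallest p were miR-145-3p (log2 fold change -0.51), miR-133a-5p (-0.65), miR-499-5p (-0.70) and miR-378a-5p (-0.52). In the let-7 family, 4 of 19 tested members fell and 15 did not pass (camera adjusted p = 0.0226; 3 members adjusted over the list alone). The 4 were let-7b-3p, let-7c-2-3p, let-7a-1-3p and let-7c-1-3p, at -1.15, -0.87, -0.87 and -2.21. The value of let-7c-1-3p rests on few counts, 47, 49 and 43 in normal replicates 1 to 3 and 0, 4 and 6 in ischemia-reperfusion replicates 1 to 3. All 4 are 3p strands, usually the less abundant product of a let-7 hairpin, and let-7c-2-3p and let-7a-1-3p have the same sequence and count as 1 signal. The calls of let-7c-2-3p and let-7a-1-3p were lost without ischemia-reperfusion replicate 2 (adjusted p = 0.0561 for each), and those of let-7c-1-3p and miR-378a-5p without any library but ischemia-reperfusion replicate 1 (0.0502 to 0.128) and normal replicate 1 (0.0713 to 0.151), respectively. The call of miR-145-3p was lost without normal replicate 2 or any ischemia-reperfusion library (0.0636 to 0.101). The count of 2 lists became 7 without normal replicate 1, 8 without normal replicate 3 and 8 without ischemia-reperfusion replicate 3. Both list calls were also lost after thinning to the smallest total (adjusted p = 0.108 for each), with the stricter filter (0.162 for each) and when miRBase-named miRNAs were tested against each other (0.946 for each). No single member of either list passed edgeR when miRBase-named miRNAs were fitted alone. The median of the literature list was -0.38 with TMM factors, -0.13 with total counts and -0.01 with factors from miRBase-named miRNAs, and that of the let-7 list -0.37, -0.14 and -0.04. Fry passed 8 lists downward. Of 10 ways to split the 6 libraries into 3 and 3, 6 gave at least 2 lists past camera, the real one included.

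Among the other families and clusters, 3 of 11 miR-30 members fell, with miR-30d-5p at -0.76 and miR-30c-5p at -0.83, and 8 did not pass; 3 members passed adjusted over the list alone. In the miR-23/27/24 clusters 3 of 9 fell, among them miR-27a-5p at -1.03, and miR-23a-3p was at 0.56 without passing (adjusted p = 0.0992). In the miR-17-92 clusters 2 of 10 fell, miR-25-3p at -0.53 and miR-106b-3p at -0.49, and the median of the 10 turned from -0.26 to 0.08 with factors from miRBase-named miRNAs. The miR-15 family and the X-linked cluster that holds miR-322 each had 1 member that fell, miR-195-3p and miR-450a-5p, of 10 and 9 tested; the median of the miR-15 family turned from -0.31 to 0.03 with those factors. None of 23 members of the Dlk1-Dio3 cluster, 7 of the miR-181 family, 5 of the miR-29 family and 4 of the miR-34 family passed edgeR, DESeq2 or limma-voom, and 1, 0, 0 and 0 of them had an unadjusted p under 0.05. The medians of the Dlk1-Dio3 cluster (-0.20) and the miR-181 family (-0.20) turned positive with total counts (0.06 and 0.04) and factors from miRBase-named miRNAs (0.18 and 0.14), and those of the miR-29 (-0.32) and miR-34 (-0.24) families with the latter alone (0.04 and 0.11). None of these lists passed camera (adjusted p = 0.0835 to 0.344). Downward calls were gained under some alternatives, fry and fits without 1 library included. They numbered 6 each for the miR-30 and X-linked lists, 4 each for miR-15 and miR-17-92, 3 for miR-23/27/24 and 2 for Dlk1-Dio3. No list passed with an estimated correlation, with the stricter filter, after thinning or with miRBase-named miRNAs alone. Adjusted over the list alone, 1 member passed in each of the miR-23/27/24, miR-15 and X-linked lists, and 0 in the miR-17-92, Dlk1-Dio3, miR-181, miR-29 and miR-34 lists. Without ischemia-reperfusion replicate 2, miR-30c-5p (adjusted p = 0.0589), miR-27a-5p and miR-450a-5p (0.0540 each) did not pass, nor did miR-450a-5p without ischemia-reperfusion replicate 3 (0.0600). The call of miR-25-3p was lost without normal replicate 2, normal replicate 3, ischemia-reperfusion replicate 1 or ischemia-reperfusion replicate 2 (0.0603 to 0.127), and that of miR-106b-3p without any library but normal replicate 1 (0.0772 to 0.183). When miRBase-named miRNAs were fitted alone, 0 members of the miR-30, miR-23/27/24, miR-17-92 and X-linked lists were called lower. In the miR-15 family 1 was, miR-195-3p, and miR-23a-3p passed as higher.

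The 8 predicted entries with the largest increases under the naming rule had log2 fold changes of 6.37 to 7.15. The largest was at 73.9 ± 22.6 CPM in normal hearts and 10510 ± 9341 CPM after ischemia-reperfusion (SD, n = 3 each; log2 fold change 7.15 ± 0.85, SE; adjusted p = 0.00217). Another was at 2.68 ± 1.54 and 289 ± 181 CPM (SD, n = 3 each; log2 fold change 6.75 ± 0.67, SE; adjusted p = 0.00125), and another at 2.00 ± 1.32 and 190.1 ± 171 CPM (SD, n = 3 each; log2 fold change 6.56 ± 1.03, SE; adjusted p = 0.00382). The other 5 had from 4 to 17 counts summed over the 3 normal libraries, and their log2 fold changes of 6.37 to 7.07 rest on those few counts. The listed sequences of the 172 higher entries had a median length of 18 bases against 22 for tested miRBase-named miRNAs, and a median of 1.96% of their counts were exact matches to the listed sequence against 15.6%. In the exact mature sequence counts alone, 19 predicted entries were higher by edgeR.

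In the authors' deposited table, 114 of 589 rows had an unadjusted p under 0.05, of which 82 were higher and 32 lower after ischemia-reperfusion. Predicted entries made up 65 of those 82, and miRBase-named miRNAs 17, with 29 miRBase-named rows lower. A false discovery rate under 0.05 was reached by 1 row of the authors' deposited table, that of miR-23b-5p, whose normalized values there are 1 in each normal library and 0 in each ischemia-reperfusion library. Some entries counted in a normal library, with 31 counts at most, have a blank normalized value there, and 0 counted entries do in ischemia-reperfusion libraries, which can raise the fold of such entries. Of 95 miRNAs past that unadjusted p and tested here with edgeR, 94 had the same sign and 81 also passed adjusted p 0.05 with that sign. For miR-122-5p the authors' deposited table gives a fold of 9.97 with p = 0.125 and for miR-195-3p a fold of 0.472 with p = 0.00145.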

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

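All tests in this part were chosen only after the results they bear on were seen. In the counts of exact mature sequences, which the comparisons do not rest on, predicted entries held 1.24% ± 0.364 of the counts in ischemia-reperfusion libraries, above the 0.799% ± 0.125 of normal libraries (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Ischemia-reperfusion replicates 1 to 3 were at 1.63%, 1.17% and 0.911%, the last close to the 0.892% of normal replicate 3.

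Predicted entries were higher after ischemia-reperfusion in 172 of 219 cases. Fewer reads alone are argued against as the cause. A higher raw count in every shallower library than in every normal one was found for 145 entries. These were 66.2% of the 219 and 84.3% of the 172, a share favoured by picking the 172 as higher. Within the ischemia-reperfusion group the predicted share fell as depth rose, from 13.6% to 7.87% and 5.46% in replicates 1 to 3. Causes that go with library yield therefore cannot be told apart from the group. Regulated miRNA processing would predict a share of exact sequences at least as high as in miRBase-named miRNAs. The median was instead lower in the 172 (1.96%, quartiles 0 to 7.46) than in miRBase-named miRNAs (15.6%, quartiles 4.46 to 36.4). It was 1.75% in all 219 tested predicted entries, most of which are the same 172. The low medians go against this explanation for many entries, but the quartiles overlapped, so it was not excluded. Fragments of 5S and 5.8S ribosomal RNA may account for part of the pattern: 3 of the 172 entries held 15 bases in a row of these RNAs and took 45.3% of the added share, while 0 miRBase-named miRNAs and 0 reversed sequences matched. The largest of the 3, which matched 5S, went from 2024 ± 656 to 33828 ± 7315 CPM (SD, n = 3 each). Other ribosomal RNAs were not searched, so the 45.3% does not cover fragments of them. The rest was not traced, and ischemia-reperfusion itself stays open as untested. Of the 10 splits of the 6 libraries, 1 gave as many calls, the real one with 224 (highest other 0). However, 10 splits are too few for a share under 0.05.

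Among miRBase-named miRNAs, 42 were lower and 3 higher. Thinning every library to the smallest total left 27 lower and 3 higher, which argues against sampling of the listed counts as the whole cause. It cannot restore tags under the smallest listed count of 2, so that effect of depth stays open. In exact mature sequence counts, with 229 entries tested, 13 miRBase-named miRNAs were lower and 6 higher (median -0.04). Scaling set by the predicted entries may account for many of the 42 lower calls, because factors from miRBase-named miRNAs gave 13 lower and 14 higher. The median of the 42 went from -0.76 (SD 0.51) to -0.41 (SD 0.51), so calls ended because the factors shifted all miRNAs of a library alike. Which scaling is right for these hearts was not settled by any value here.

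In normal replicate 1, miR-1-3p held 14.4% of the counts. Counting of miR-1b reads as miR-1-3p is argued against as the whole cause, since the sum of both was 370731 CPM of the library total there and at most 280580 in the other 5 libraries (SD 38701). Misreading of the base that differs between them (G17A, counted from the 5′ end of miR-1-3p) is argued against as the whole cause. This rests on 19 other miRNAs with the same base as miR-1b at that place. Against the other normal libraries, their exact share moved by a median of -0.13 on the log2 scale (quartiles -0.19 to 0.01). For 96 miRNAs with another base there it moved by -0.01. If all miR-1-3p of normal replicate 1 came from miR-1b, -0.71 would be needed. Measured against the other normal libraries, which also held miR-1-3p, the needed size is smaller, so the margin is narrower. The 19 moved further than the 96, so misreading of part of the reads stays open. A difference of this heart or of its library preparation stays open, and no biological explanation was tested.

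For the lists past camera, 6 of the 10 splits gave as many, with 2 for the real split and 4 for the highest other. The number of lists called was thus no higher than other groupings of the same libraries gave. It is no evidence of a difference between the groups, and 10 splits are too few for a share under 0.05 in any case.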

How the results depend on the processing

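The other count columns, every precursor row, 1 row per mature sequence, miRBase-named miRNAs alone, scaling on them and tests after thinning were chosen only after the results were seen. For 67 named miRNAs, 1574 values under alternatives gave 1228 with the same direction and side of the threshold, 229 that lost a call, 48 that gained one and 69 with the opposite direction. All calls ranged from 8 to 334 against 224. The cause of each change below was not tested unless stated.

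The stricter filter, which tests fewer entries, gave 126 calls, 86 predicted entries higher and 0 lists (4 unadjusted), with miR-30a-5p at 0.059, miR-21-5p at 0.015 and miR-155-5p at 0.027. No filter gave 8 miRBase-named miRNAs higher, 11 lists and miR-15b-5p at -0.019. Exact mature sequence counts, with fewer entries tested, gave 38 calls, 13 miRBase-named lower, 6 higher, 19 predicted entries higher and 40 shared signs with the authors' deposited table, with miR-1b at 0.16, miR-143-3p at 0.23, miR-148a-3p at 0.66, miR-133a-3p at 0.11, miR-21-5p at 0.10, miR-210-3p at 0.19, miR-320-3p at 0.30, miR-29a-3p at 0.10, miR-155-5p at 0.69, miR-145-3p at 0.027 and miR-26b-5p at -0.049. Most abundant sequence counts gave 118 calls, 24 miRBase-named lower, 5 higher, 84 predicted entries higher and 62 shared signs with the authors' deposited table, with miR-143-3p at 0.18, miR-21-5p at 0.091 and miR-223-3p at 0.058. Thinning, which lowers depth and with it the entries tested from 524 to 358, gave 127 calls, 27 miRBase-named lower, 93 predicted entries higher, 0 lists (3 unadjusted) and miR-30a-5p at 0.016; miRNAs with at least 1 count then differed by 138 between groups and those with at least 10 by 123, against 28.7 and -2.

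miRBase-named miRNAs alone gave 8 calls, 3 lower, 5 higher and 0 lists (2 unadjusted). The direction of the lists liver and epithelial and smooth muscle and fibroblast turned (adjusted p = 0.215 each), as did neural and endocrine, miR-181 and Dlk1-Dio3 (0.944 each) and miR-34, miR-17-92, ischaemia-reperfusion literature, miR-29 and miR-23/27/24 (0.946 each). In that fit miR-1b was at 0.19, miR-143-3p 0.23, miR-148a-3p 0.038, miR-30a-5p 0.30, miR-133a-3p 0.049, miR-21-5p 0.25, miR-320-3p 0.035, miR-29a-3p 0.081, miR-195-5p 0.0011, miR-146a-5p 0.075 and miR-155-5p 0.28. Scaling on them gave 13 lower, 14 higher, miR-1b 0.19, miR-143-3p 0.23, miR-148a-3p 0.038, miR-30a-5p 0.30, miR-133a-3p 0.049, miR-21-5p 0.25, miR-320-3p 0.034, miR-29a-3p 0.081, miR-146a-5p 0.075 and miR-155-5p 0.25. Upper-quartile factors gave 145 lower, miR-26a-5p -0.36, miR-15b-5p -0.47, miR-505-3p -0.071 and miR-26b-5p -0.27. Total counts gave 16 lower, 10 higher, miR-1b 0.094, miR-143-3p 0.12, miR-30a-5p 0.18, miR-21-5p 0.14 and miR-155-5p 0.16. RLE factors gave miR-30a-5p 0.0605, miR-21-5p 0.019 and miR-155-5p 0.025, and DESeq2 gave 7 higher with 0.0605, 0.019 and 0.038 for the same miRNAs. limma on the authors' normalized values gave 17 lower, 11 higher, miR-1b 0.081, miR-143-3p 0.11, miR-30a-5p 0.18, miR-21-5p 0.14, miR-223-3p 0.21 and miR-155-5p 0.19. A minimum of 1 log2 unit gave 11 lower. An estimated correlation gave 0 lists (0 unadjusted), and fry 8, with liver and epithelial turned (adjusted p = 0.146). Median log2 fold changes of all entries were -0.17 with TMM, -0.06 with RLE, -0.67 with upper-quartile factors, 0.07 with total counts and 0.18 with scaling on miRBase-named miRNAs.

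With the replicate block, 152 calls, 15 miRBase-named lower and 2 lists were found. Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.24, 0.01 and -0.16, and 0 of 6 libraries correlated best with its own number.

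Leaving out 1 library gave 8 to 67 miRBase-named lower (67 without normal replicate 1, 19 and 27 without normal replicates 2 and 3, 21 and 8 without ischemia-reperfusion replicates 1 and 2) and 2 to 7 higher (5 without normal replicate 1, 7 without ischemia-reperfusion replicate 3). Lists past camera numbered 2 to 8 (7 without normal replicate 1, 8 without normal replicate 3, 8 without ischemia-reperfusion replicate 3), with liver and epithelial at an adjusted p of 0.496 to 0.940, its direction upward without ischemia-reperfusion replicate 2 (0.940). Log2 fold changes ranged from -0.31 to 0.10 for miR-1b, -0.26 to 0.035 for miR-143-3p, -0.0083 to 0.29 for miR-26a-5p, -0.21 to 0.058 for miR-30a-5p, -0.26 to 0.053 for miR-21-5p, -0.27 to 0.21 for miR-15b-5p and -0.34 to 0.34 for miR-155-5p.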

Other observations

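The test of the less abundant arms was fixed before its value was computed, although the pattern had been noticed in the data; the fit of miRBase-named miRNAs alone was chosen only after the results were seen, and so were the miRNAs named here. Further miRNAs past edgeR's adjusted p 0.05 fell that belong to none of the lists. miR-10b-5p, encoded in a Hox cluster, went from 768 to 396 CPM (log2 fold change -0.96; adjusted p = 0.0239), miR-361-3p from 566 to 323 CPM (-0.81; adjusted p = 0.00621) and miR-151-3p from 1405 to 823 CPM (-0.77; adjusted p = 0.00705). Both arms of miR-139 fell, miR-139-5p by 0.76 and miR-139-3p by 1.27 on the log2 scale (edgeR adjusted p = 0.0239 and 0.0496), and so did both arms of miR-99b, by 0.61 and 0.68 (adjusted p = 0.0175 and 0.0318). None of these 7 passed edgeR when miRBase-named miRNAs were fitted alone (adjusted p = 0.0963 to 0.344), and 5 had an unadjusted p under 0.05 there. Leaving out 1 library ended the call of miR-139-3p in each of 6 cases (adjusted p = 0.0666 to 0.182), of miR-99b-3p without any library but normal replicate 1 (0.0600 to 0.123), and of miR-139-5p without normal replicate 2, normal replicate 3, ischemia-reperfusion replicate 1 or ischemia-reperfusion replicate 2 (0.0630 to 0.0987). The calls of miR-10b-5p and miR-99b-5p were lost without normal replicate 2, ischemia-reperfusion replicate 1 or ischemia-reperfusion replicate 2 (0.0707 to 0.101 and 0.0516 to 0.0784).

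In that fit, miR-505-3p, miR-23a-3p and miR-26b-5p were higher, with log2 fold changes of 0.80, 0.90 and 0.59 (edgeR adjusted p = 0.0419, 0.0497 and 0.0498). In the fit of all entries they were at 0.45, 0.56 and 0.24 and did not pass (adjusted p = 0.0812, 0.0992 and 0.186). Calls were gained under 9 alternatives for miR-505-3p, 6 for miR-23a-3p and 4 for miR-26b-5p, that fit included. All 3 passed with total counts (adjusted p = 0.0224, 0.0258 and 0.0156) and with factors from miRBase-named miRNAs (0.0124, 0.0218 and 0.0107), and miR-23a-3p also without normal replicate 1 (0.0338). With upper-quartile factors miR-505-3p and miR-26b-5p were at -0.071 and -0.27, and in exact mature sequence counts miR-26b-5p was at -0.049.

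In 80 miRNAs with both arms tested, the less abundant arm lay below its partner in 49, with a median difference of -0.19 log2 units. Where it had at least 100 counts in every library, the median was -0.20 over 15 pairs (quartiles -0.40 to 0.13), too wide to decide whether fewer reads in shallower libraries play a part.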
